A study of Mus musculus with 13 samples.

How the data were processed

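Bulk RNA sequencing was carried out on 13 mammary tumours, 7 from mice given vehicle and 6 from mice given OCA. The tumours grew from MDA-MB-231 cells, an established human triple-negative breast cancer line, placed in the mammary gland of female NSG mice, a strain that lacks mature lymphocytes. The series text calls these mice immunocompetent, which does not describe that strain. OCA is obeticholic acid, a bile acid analogue that activates the nuclear receptor FXR. Per the labels' protocols, OCA was given by gavage each day at 30 mg per kg, and the vehicle was 40% DMSO with 60% polyethylene glycol. The protocols count 8 vehicle and 7 OCA mice in treatment, of which 7 and 6 were sequenced, from RNA with an integrity number above 6 and with paired reads of 150 bases. A paclitaxel arm was treated but not sequenced, per the labels. The labels give each library its own number and the protocols count mice, so the libraries were taken as separate animals. Replicates are numbered within each group in accession order, so a replicate number pairs no vehicle library with an OCA library.

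The submitters' processing notes name FastQC, STAR, Salmon and DESeq2 without versions, and the human genome build GRCh38.p14. The transcript annotation is not given in the sources used here. Per the file headers, the authors deposited for each library a length, an effective length, a TPM value and an estimated count of reads for each of 244939 transcripts. The estimated counts need not be whole numbers, because reads that match several transcripts of a gene are shared among them by a statistical model. The uncertainty of that sharing was not used here, so the spread between libraries of a transcript holds assignment error as well as biological variation. The deposited TPM values were not tested, since TPM keeps no record of depth. The effective length was identical in all 13 libraries, and 249 bases below the length for every transcript over 2000 bases. A length offset would therefore be equal in every library and was not fitted. Reads from mouse cells in the tumours were not separated here from reads of the human cells, and how the authors treated them is not given in the sources used here.

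The files identify transcripts by ID and do not pair these IDs with gene names, and the reference annotation used here is of the mouse. Transcripts were therefore not summed to genes. The test planned for this case before the data were examined, the same test on single transcripts, is the main result. Also for want of gene names, the 39 gene lists fixed before the data were examined, the level of host cell markers, the mitochondrial share of reads and a restriction to protein-coding genes were not analysed here. The rule for named items, fixed at the same time, takes the item with the smallest p in each direction and, where none passes the threshold, the 5 with the smallest p in each direction among those with a mean of at least 1 CPM. IDs without a gene name are limited to 2 in each direction, so the first of each kind is given. The parts of the rule that need gene symbols were not applied.

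Estimated counts were rounded to whole numbers. Transcripts with low counts were removed by edgeR's filterByExpr with its defaults, a minimum count of 10 in enough libraries and a minimum total of 15. Library sizes were scaled by TMM, and OCA was compared with vehicle by edgeR's robust quasi-likelihood F test, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. CPM values use the TMM-scaled library sizes. A standard error of a log2 fold change was taken as its size divided by the square root of F. Where all libraries of a group held 0 reads, the fold is a lower bound against a floor of 3 counts per library, which covers counting error only. Total reads, transcripts with at least 1 estimated read and the share of reads on the 20 highest transcripts were compared by two-sided exact permutation tests over all 1716 splits of the libraries. Another measure, the share of reads on transcripts of 4000 bases or more, was added after seeing the data, from shares in several classes of length and of ID number per library. Its p does not cover that search. These 4 measures were adjusted together. Principal components were computed on log2 CPM with a prior count of 2. The label numbers of the libraries fall into 2 series, 4340 to 4351 with 3 vehicle and 4 OCA libraries, and 4371 to 4385 with 4 vehicle and 2 OCA libraries. What the numbers record is not given, and the series was treated as a possible batch.

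The alternatives planned before the data were examined were DESeq2, limma-voom with and without sample weights, edgeR without robust estimation, 3 other scalings, 3 other low-count filters, a minimum fold change, the label series or 1 surrogate variable as a covariate, and leaving out each library. Those added after seeing the data were DESeq2 after the low-count filter, the 3 libraries that stand apart on the first component as a covariate or left out, sums of 2, 5, 10, 20 and 50 neighbouring transcripts in file order, and, for the library measures, subsets of libraries, thinning to the lowest total and other length limits. The tools were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, sva 3.50.0, Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9. The edgeR test was tested on simulated data with the means, library sizes and dispersions of the 74973 transcripts of this comparison. Among 50 randomly chosen transcripts changed by each size, it recovered 2% of those changed 1.5-fold, 8% at 2-fold, 38% at 4-fold and 54% at 8-fold. Among transcripts with a mean of at least 10 CPM these shares were 12%, 70%, 94% and 96%. Changes of all 4 sizes were planted together in each simulation, and counts were drawn independently, without structure shared by libraries. The 2 simulations gave 55 and 143 calls, which makes the adjusted threshold easier to pass than with 0 calls. These shares can therefore overstate what was detectable here.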

Results

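RNA was measured in 13 MDA-MB-231 tumours, 7 from vehicle-treated and 6 from OCA-treated mice. The vehicle libraries held 34015674 to 49844746 estimated reads (mean 42565713 ± 6980000 SD, n = 7) and the OCA libraries 44150968 to 50596490 (mean 47465722.5 ± 2090000 SD, n = 6). These totals did not differ beyond the spread between libraries (exact permutation test, p = 0.141, adjusted p = 0.188 over 4 measures). Vehicle replicates 2, 3 and 5 were the 3 libraries under 40000000 reads, and all 3 belong to the upper label series. Low depth was therefore found only in vehicle libraries of that series. Within the lower label series the OCA libraries held 223300 reads more on average (exact p = 0.829), and within the upper series 8350000 more (exact p = 0.333). Without vehicle replicates 2, 3 and 5 the sign turned, with OCA minus vehicle at -461800 reads on average (exact p = 0.762). These libraries were left out for their low totals, so that turn follows from the choice. At least 1 estimated read was found for 100453 ± 2520 transcripts in OCA tumours (SD, n = 6) and 97279 ± 2540 in vehicle tumours (SD, n = 7). This difference of 3174 transcripts had an exact permutation p of 0.0466 and missed the threshold after adjustment (adjusted p = 0.0932), with 5 of 6 OCA libraries above the vehicle mean. Without vehicle replicate 7 it was 3778 (exact p = 0.0216, adjusted p = 0.0432) and without OCA replicate 2 it was 4120 (exact p = 0.00884, adjusted p = 0.0177). Without the 3 vehicle libraries under 40000000 reads it was 1506 (exact p = 0.329, adjusted p = 0.658). Within the lower series it was 2084 (exact p = 0.0857) and within the upper series 2586 (exact p = 0.333). The 20 highest transcripts took 7.84% ± 0.306 of the reads in OCA (SD, n = 6) and 7.86% ± 0.267 in vehicle libraries (SD, n = 7), with an exact permutation p of 0.917. Within the lower and upper label series, OCA minus vehicle was -0.0568 and 0.158 percentage points (exact p = 0.857 and 0.467). Across transcripts with a mean of at least 1 CPM, which are not independent replicates, pairs of libraries correlated at r = 0.846 to 0.905 on the log2(CPM + 0.5) scale, and no pair was close enough to be a single library deposited again.

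The comparison of OCA with vehicle addresses whether dosing with OCA, an activator of FXR, alters expression in tumours of this line, in a study whose title concerns tumour burden. No transcript passed the adjusted threshold by edgeR's quasi-likelihood test. The smallest p among transcripts higher in OCA tumours was that of ENST00000680456.1, and among those lower that of ENST00000492466.2. Among transcripts with a mean of at least 1 CPM they were those of ENST00000429888.5, higher in OCA, and ENST00000413266.6, lower. Of 74973 transcripts tested, 0 had an adjusted p under 0.05, and the smallest adjusted p was 0.459. At an unadjusted p under 0.05 there were 2078 transcripts (2.77%), 1026 higher and 1052 lower in OCA. DESeq2 called 410 transcripts without a low-count filter (131 higher, 279 lower) and 12 after the filter edgeR used (5 higher, 7 lower). Both DESeq2 fits kept that tool's defaults, which leave some transcripts of low mean count without an adjusted p. Limma-voom called 0. With the label series as a covariate edgeR called 0, with 1702 at an unadjusted p under 0.05. It called 1 transcript without vehicle replicate 7, 1 without OCA replicate 6 and 0 without any other single library.

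**Figure D1:**
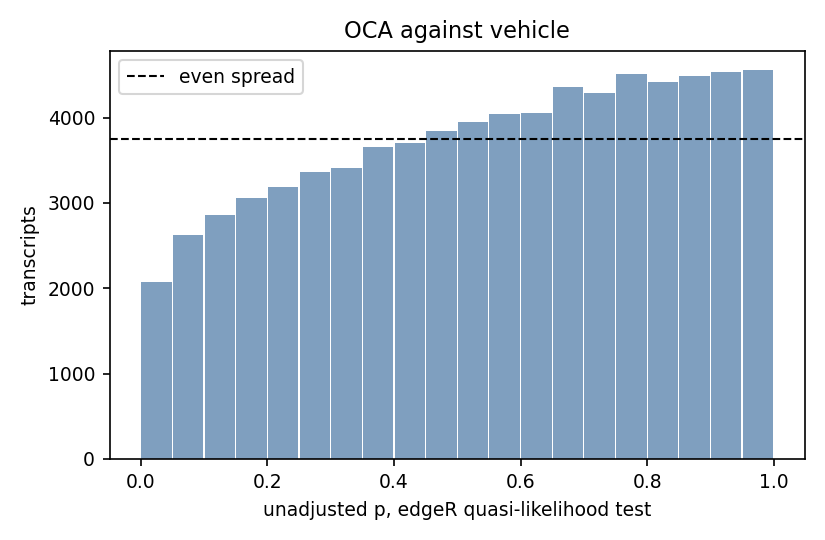
Histogram of the unadjusted p of 74973 transcripts from edgeR's test of OCA (n = 6) against vehicle (n = 7), in 20 bins. The x axis is p and the y axis the number of transcripts. The dashed line is the number per bin if p were evenly spread, and the lowest bin, with 2078 transcripts, lies below it. The highest bin holds 4556. Over other splits of the libraries a median of 1736 transcripts had an edgeR p under 0.05, also below the line. The low first bin is therefore not particular to treatment, and these p values lie higher than an even spread.

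ENST00000429888.5, a transcript of 7325 bases, measured 49.7 ± 5.84 CPM in OCA tumours (SD, n = 6) and 32.8 ± 5.25 CPM in vehicle tumours (SD, n = 7). Its log2 fold change was 0.60 (SE 0.12, edgeR adjusted p = 1), and the 2 groups did not overlap, at 43.4 to 58.4 against 22.5 to 37.9 CPM. ENST00000413266.6, of 2671 bases, measured 23.3 ± 4.14 CPM in OCA (SD, n = 6) and 41.6 ± 8.64 CPM in vehicle tumours (SD, n = 7), a log2 fold change of -0.83 (SE 0.15, edgeR adjusted p = 1). Its groups did not overlap either, at 17.6 to 28.3 against 29.3 to 56.6 CPM. ENST00000680456.1, of 1836 bases, measured 1.39 ± 0.547 CPM in OCA (SD, n = 6) and 0.267 ± 0.0990 CPM in vehicle tumours (SD, n = 7). It was 5.23-fold higher by the group means, with a log2 fold change of 2.37 (SE 0.39, edgeR adjusted p = 0.796), and rested on 34.6 to 105 estimated reads per OCA library and 3.54 to 15.8 per vehicle library. ENST00000492466.2, of 899 bases, had 0 estimated reads in all 6 OCA libraries and 4.90 to 45.2 in the 7 vehicle libraries. Its vehicle mean of 0.605 ± 0.292 CPM (SD, n = 7) was at least 9.44-fold above the mean floor of 0.0641 CPM that 3 counts per library set in OCA (edgeR adjusted p = 0.459). With the label series as a covariate, the log2 fold changes of ENST00000680456.1, ENST00000429888.5 and ENST00000413266.6 were 2.34, 0.60 and -0.85, and the adjusted p of each of the 4 was 1 by edgeR. Without a low-count filter, DESeq2 gave these 4 transcripts adjusted p values of 1.48e-07 for ENST00000680456.1, 0.00125 for ENST00000429888.5, 2.83e-10 for ENST00000492466.2 and 0.000114 for ENST00000413266.6. The 4 were picked for their smallest p, so the lack of overlap between their groups is no independent support. Of 72596 transcripts, 0.117% had groups that did not overlap, the share that chance gives. DESeq2 without a filter also called 388 to 516 transcripts in other splits of the libraries. Transcripts of 1 gene share reads, so the values of a single transcript are uncertain in all 13 libraries.

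**Figure D2:**
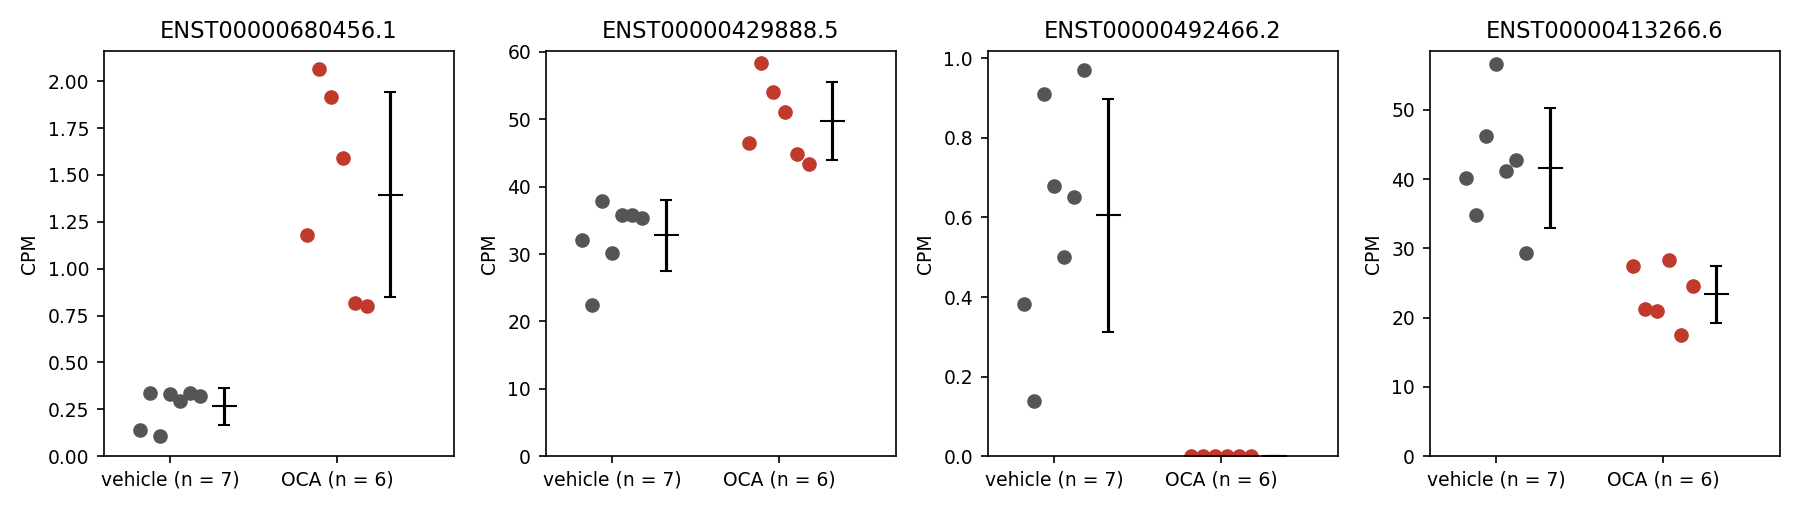
CPM of the 4 named transcripts in each library, with vehicle (n = 7) in grey and OCA (n = 6) in red. Each point is 1 tumour, and the bar beside each group is the mean ± SD. The groups do not overlap in any of the 4, which were picked for their smallest p, and ENST00000492466.2 is at 0 in all 6 OCA libraries.

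Among the 14710 transcripts with a mean of at least 10 CPM, the median size of the log2 fold change was 0.112 and the median standard error 0.142. More than a 2-fold difference was estimated for 41 of them (0.279%), and 834 (5.67%) had an unadjusted edgeR p under 0.05. That share was not set against other splits of the libraries. The common dispersion over all tested transcripts was 0.563, a coefficient of variation of 75.1% between libraries of a group. Of the tested transcripts, 12179 (16.2%) had 0 reads in 3 or more libraries. Simulated data used the fitted dispersion of each transcript. There, edgeR recovered 70% of the 2-fold changes among transcripts of at least 10 CPM and 8% among transcripts taken at random. Many changes were planted together, which eases the adjusted threshold, so these shares can overstate what this comparison could detect. At this depth and spread, 2-fold changes of transcripts taken at random, most of which lie under 10 CPM, were mostly not detectable. Weakly expressed transcripts were not simulated on their own.

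Long transcripts held a larger share of the reads in OCA tumours. Transcripts of 4000 bases or more took 28.0% ± 0.743 of the reads in OCA (SD, n = 6) and 26.6% ± 0.564 in vehicle libraries (SD, n = 7). The difference of 1.41 percentage points was as large in 6 of the 1716 splits of the libraries (exact permutation test, p = 0.0035, adjusted p = 0.014 over 4 measures). All 6 OCA libraries lay above the vehicle mean, and 4 lay above every vehicle library. The measure itself, with its length limit, was chosen after seeing the data, from shares in several classes of length and of ID number. Neither the exact p nor the adjusted p covers that search. Within the lower label series the difference was 1.29 points (exact p = 0.0857, where 0.0286 is the smallest possible), and within the upper series it was 1.18 points (exact p = 0.0667, the smallest possible). In 10 equal classes of length, among transcripts with a mean of at least 1 CPM, the median log2 difference between OCA and vehicle was -0.02 in the shortest class, -0.05 in the class from 1063 to 1567 bases and 0.08 in the longest.

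**Figure D3:**
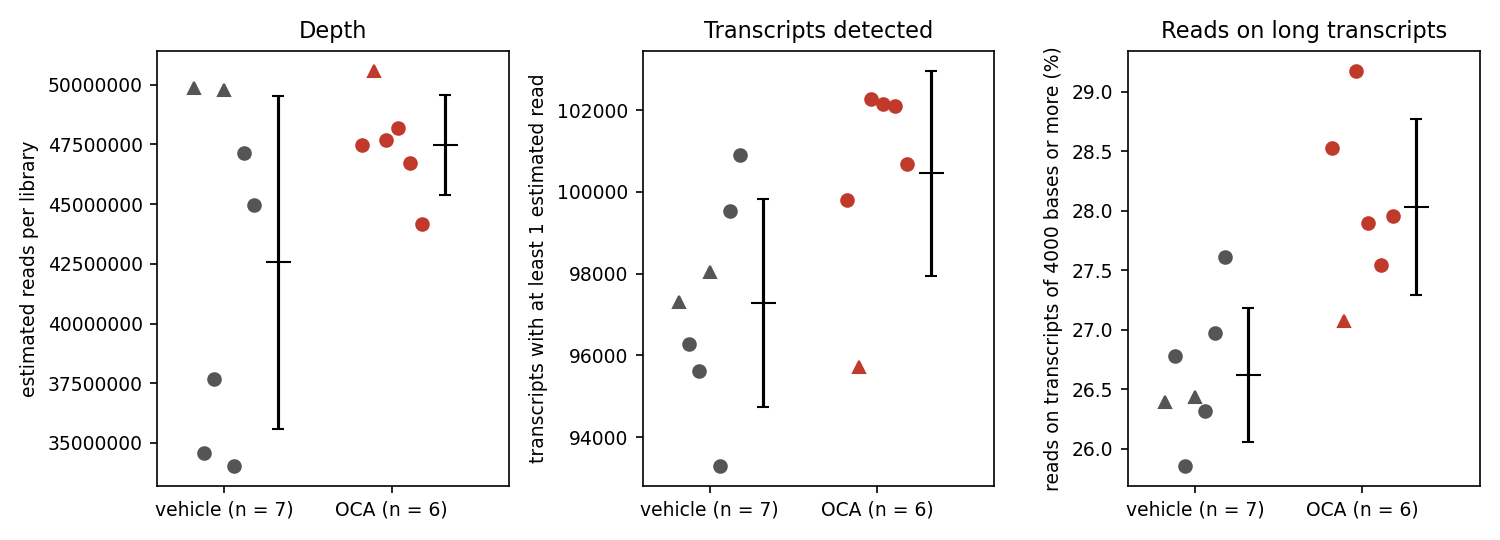
Total estimated reads, transcripts with at least 1 estimated read, and percent of reads on transcripts of 4000 bases or more, for each vehicle (grey, n = 7) and OCA (red, n = 6) library. Bars are mean ± SD, triangles mark the 3 libraries set apart on the first principal component, and no y axis starts at 0. The share on long transcripts runs from 27.1% to 29.2% in OCA and from 25.8% to 27.6% in vehicle libraries.

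The first principal component held 14.4% of the variance and did not follow treatment (exact permutation test, p = 0.992). It set vehicle replicates 1 and 4 and OCA replicate 2, at scores of 216 to 231, apart from the other 10 libraries, at -126 to -21.3. The second component held 9.77% of the variance (exact p = 0.0559, adjusted p = 0.224 over 4 components), and the next components, 3 and 4, had exact p values of 0.325 and 0.854. Treatment accounted for 8.06% of the variance of 72596 transcripts with a mean above 0.3 CPM, against a median of 8.21% over all 1716 splits (exact permutation test, p = 0.598). The split by label series accounted for 8.18% (exact p = 0.522). With the 3 libraries left out, edgeR called 1 transcript, lower in OCA, and with them as a covariate it called 0. With the 3 libraries left out, the share of reads on long transcripts differed by 1.52 percentage points (exact permutation test, p = 0.0159).

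**Figure D4:**
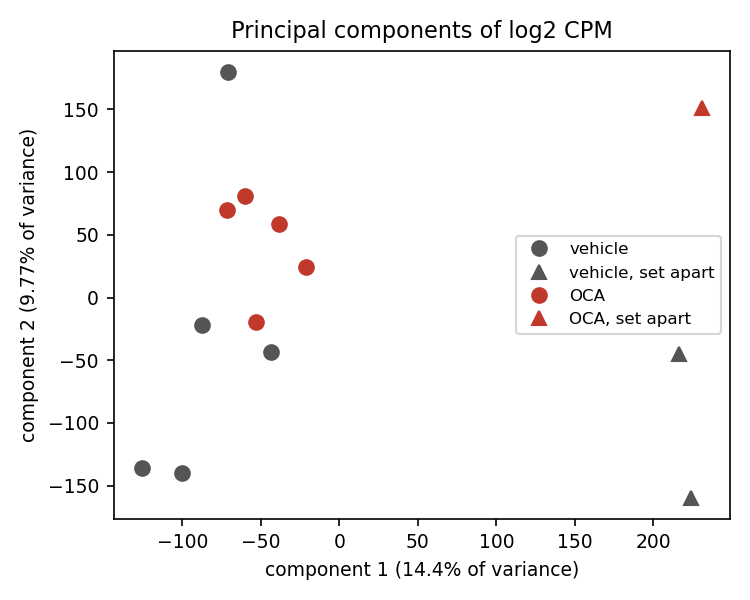
Scores of the 13 libraries on the first (x axis) and second (y axis) principal component of log2 CPM, with vehicle in grey and OCA in red. Triangles mark vehicle replicates 1 and 4 and OCA replicate 2, whose first-component scores of 216 to 231 lie above the rest.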

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

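No library was an outlier in its group by Dixon's test at the 95% level. OCA replicate 2 fell just short of the limit in transcripts with at least 1 read. It held 95722, against 99807 to 102262 in the other OCA libraries. The 15 tests covered the 4 library measures and the CPM values of the 4 named transcripts in each group, except ENST00000492466.2 in OCA, where all values are 0. About 0.75 outliers would be found by chance in that many tests. A test for 1 outlying value does not look for several libraries that stand apart together.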

How the results depend on the processing

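The length offset was not fitted, since it would be equal in every library, and the alternatives that need gene names (gene sums, biotypes, host markers as a covariate, gene lists) were not run. The added settings listed in the processing summary were chosen after seeing the data. The count of 0 transcripts past the threshold stayed at 0 in 29 of 34 alternatives. Among these, the minimum fold change could only give 0, since it only removes calls, and the sums of neighbouring transcripts do not stand for genes. It became 410 with DESeq2, 12 with DESeq2 after the low-count filter (added) and 1 in the 10 libraries left without the 3 set apart (added). Leaving out each library in turn gave 0 to 1, with 1 transcript higher in OCA without vehicle replicate 7 and another 1 without OCA replicate 6. Each of these 3 single calls is outside the named transcripts and had 0 reads in 5 or more libraries of a group. The 2078 transcripts at an unadjusted p under 0.05 became 4977 with DESeq2, 3130 with DESeq2 after the filter, 3707 and 4077 with limma-voom without and with weights, and 16150 without a low-count filter, where 163074 transcripts were tested. They became 1019 where a mean of at least 5 CPM left 22092 transcripts. Leave-one-out fits gave 1585 to 2995. The division into higher and lower moved with limma-voom, to 2295 higher and 1412 lower. The cause of the differences between tools stays open. The 4 named transcripts kept their direction in every alternative that held them. Their adjusted p stayed above 0.05 outside DESeq2, which called all 4 without a filter and ENST00000429888.5 and ENST00000413266.6 after it. DESeq2 after the filter gave the other 2 no adjusted p, while their unadjusted p were 5.87e-10 for ENST00000680456.1, with its log2 fold change at 2.38, and 1.15e-12 for ENST00000492466.2, so the missing calls do not show a loss of the difference.

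The difference in transcripts with at least 1 read, 3174, passed the adjusted threshold in the 10 libraries (4276, adjusted p = 0.0476) and ranged from 2508 to 4120 with each library left out. It fell to 1506 without the 3 vehicle libraries under 40000000 reads (exact p = 0.329, adjusted p = 0.658). The difference in total reads, OCA minus vehicle, then turned to -461800 (exact p = 0.762), which follows from leaving out libraries for their low totals. The difference in transcripts with at least 1 read was 2566 after thinning to the lowest total, 34015673 reads (exact p = 0.0746). Thinning used estimates rounded to whole numbers, so 2566 and 3174 differ in the counting rule as well as in depth. The difference in the share on long transcripts, 1.41 points, stayed positive in all 20 alternatives, from 1.181 to 1.603. It missed the adjusted threshold within either label series (1.29 and 1.18) and without the 3 vehicle libraries under 40000000 reads (1.18), where fewer libraries were compared. In the upper series no grouping could pass, since the smallest possible exact permutation p is 0.0667. In the lower series it is 0.0286 before adjustment over the measures. The misses within the series therefore do not speak against the difference.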

Other observations

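The tests of which explanation holds were chosen after the results were seen, except the counts of edgeR and DESeq2 calls over other splits of the libraries, which were set before those counts were made. The DESeq2 splits after the low-count filter were added once some of their counts had been seen, and the unfiltered DESeq2 splits are the first 8 of a longer draw, limited for run time after that draw had been seen. The rest of that draw, not used here, also held splits with as many calls as the real one, some above the highest given below.

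A count of 0 edgeR calls cannot be set against other groupings of the libraries, since any split gives at least 0, as all 100 splits of the 13 libraries into groups of 7 and 6 did, the real one included. Of the other splits 24 gave at least 1 call, and the highest gave 5. For the 2078 transcripts at an unadjusted p under 0.05, 36 of the 100 splits gave as many, with a median of 1736 and a highest of 4356 among the other splits, so chance cannot be excluded. The split that follows the label series, which has the same group sizes, gave 1 call and 1521 such transcripts. Transcripts whose 2 groups do not overlap numbered 85 (53 higher and 32 lower in OCA) of 72596, or 0.117%, the share that chance gives. As many or more were found in 544 of all 1716 splits, with 411 in the highest other split, and chance cannot be excluded. That other split put vehicle replicates 1, 4 and 6 with OCA replicates 3, 4 and 6, and takes the libraries from the top of the first principal component down, except OCA replicate 2, which scored highest. On component 3 its vehicle replicates 4 and 6 and OCA replicates 3, 4 and 6 scored lowest, at -127.88 to -78.63, but vehicle replicate 1 scored 79.3. In 50 shuffles of each transcript's values over the libraries the highest split reached 107 to 123, so transcripts varied together across libraries. Each transcript was shuffled on its own, which also removes the correlation between transcripts of 1 gene that share reads. The shuffles therefore cannot tell a structure of the libraries from such correlation. Which component that split follows was not tested. For the share of variance between the groups, 1027 of the 1716 splits were as large.

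DESeq2 without a filter called 410 transcripts where edgeR called 0. Of the called transcripts, 86.6% had 0 reads in 3 or more libraries, against 36.0% of all 109259 transcripts with an adjusted p, and 345 were at 0 in every library of 1 group. These zeros cannot be told apart from an effect of treatment, since a transcript switched on or off by OCA would show them too, and 53 of the 410 had no library at 0. The median size of the log2 fold change of the 410 was 22.1, which is not a measured fold where 1 group holds 0 reads. The set edgeR tested held 64 of the 410, all 64 with an unadjusted edgeR p under 0.05. All 12 transcripts called after the low-count filter were among the 410, and none of the 12 had a library at 0 reads. By its defaults DESeq2 also withheld adjusted p values, in the unfiltered fit from 53815 of 163074 transcripts. After the filter it withheld them from ENST00000680456.1 and ENST00000492466.2. The drop from 410 to 12 can therefore not be credited to edgeR's filter alone. In 8 splits of the libraries, the real one included, DESeq2 gave 410 calls or more in 5. The other splits gave 388 to 516 calls, with a median of 431. The real count lay within that range, so chance cannot be excluded for it, and a share under 0.05 could not be reached with 8 splits. After the filter, 33 of 40 splits gave 12 calls or more, with 158 in the highest other split, so chance cannot be excluded for these. An effect of OCA on single transcripts stays open, since neither these splits nor edgeR's test, which called 0, can exclude it.

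Vehicle replicates 1 and 4 and OCA replicate 2 shared 273 transcripts at 0 reads that each of the other 10 libraries held at more than 20, against 22 the other way round. The highest count for any of the other choices of 3 libraries among the 286 was 14. These transcripts were short, with a median of 571 bases, and weak, with a median of 1.99 CPM in the 10 libraries. Lower depth is argued against, since the lowest total of the 3, 49764198 reads, lies above the highest of the others, 48186645, and so is treatment, since 2 of the 3 are vehicle and 1 is OCA. A transfer of the reads to the 5 neighbouring rows on each side in the file was examined for 42 transcripts. These held at least 30% of the CPM of themselves and these rows in the 10 libraries, but not nearly all of it. A transfer is argued against for the 42 as a set, since these neighbours gained a median of -0.0445 on the log2 scale, where 0.77 was needed. The 95% bootstrap interval, -0.27 to 0.17, resampled transcripts, so it holds no spread between libraries. For 8 of the 42 the gain reached 50% or more of what was needed, so a transfer stays open for these, as it does for the transcripts not examined. A transfer within a gene to rows further away stays open for all, since neighbouring rows vary together only weakly (median r = 0.112 for rows next to each other). The same 3 libraries also differed in a technical measure, the share of nonzero estimates that were whole numbers. It was 13.2%, 13.5% and 13.3% in vehicle replicates 1 and 4 and OCA replicate 2, against 11.9% to 12.7% in the other 10. The origin of that difference was not tested. A batch of library preparation or a subset of the tumour cells stays open as a candidate explanation, and no biological one was tested beyond treatment.

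The larger share of reads on long transcripts in OCA tumours is a hypothesis found in these data. Very abundant transcripts are argued against as its source, since the difference was 1.405 points without the 1000 highest (exact permutation p = 0.00117). So are the 3 libraries set apart, since it was 1.52 points without them (exact p = 0.0159), and the shallow vehicle libraries, since it was 1.18 points without these (exact p = 0.0381, adjusted p = 0.152 with 4 vehicle libraries left). RNA integrity cannot be told apart from an effect of treatment. The median change followed length with a Spearman rho of 0.77 over the 10 classes of length, without a steady rise over the shortest 5, and the integrity number of each library was not used here. A contribution of mouse reads also stays open, and was not tested.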
